A study of Homo sapiens with 95 samples.

How the data were processed

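Total RNA from 95 kidney allograft biopsies was amplified, labelled with biotin and hybridized to Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per biopsy, with the biopsy core kept in an RNA-preserving solution, per the labels' protocols. The deposited values are log2 levels, as judged from their range of 0 to 14.06. How the authors summarized the probes and put the arrays on a common scale is not given in the sources used here. Each array had a lowest value of exactly 0, and 0.227% of all values were 0, so the deposited log2 values had been floored. The table holds 54675 probe sets, 62 of them controls.

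Probe sets were named through the platform annotation, with symbols updated through gene identifiers against a RefSeq gene table where these matched (41037 probe sets). There were 41091 probe sets with 1 gene symbol, 1801 with several and 11721 with none, and the last 2 kinds were not named. Genes whose probe sets carry several symbols therefore do not appear, those of complement component C4 among them. No genome was used and no coordinates are given. Probe sets of sex-linked genes (103) were removed before any test. Genes on a list fixed before the data were examined, at which arrays can read inherited variants, were tested and are not named. The list does not hold every polymorphic gene, and HLA-DPB1 is not on it.

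The rule set before the data were examined was to use the values as deposited unless array medians differed by more than 0.5. They ran from 3.831 to 4.687, a gap of 0.856, so quantile normalization (limma) is the main setting and the deposited scale an alternative. Probe sets with a mean under the 25th percentile of all (a log2 level of 3.12) were left out. Each gene was represented by its brightest probe set with a single symbol, which left 16181 genes. Correlations between arrays ran from 0.815 to 0.965, so no array was a copy of another. No count of molecules limits the precision of an array. The number of arrays limits it, and so do dim or floored values and the quality of the RNA.

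Groups were taken from the labels: donor type, time and the named sets (18 training, 10 test set 1, 18 test set 2, 60 test set 3, and 7 called paired, of which 5 carry no other set name). All 95 arrays were used. Tests were limma lmFit and eBayes on log2 values, two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The baseline comparison of donor types had the set as a covariate, and the post-transplant comparison had the time point. Changes after transplantation were tested within each donor type without pairing. The interaction of donor type and phase was fitted on all 95 arrays. Change with time among living-donor biopsies was tested with limma's F test and between 24 and 3 months. For training calls, test set 1 was tested over these genes alone.

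Before the data were examined, 33 gene lists were fixed (5 of complement, 16 of other pathways and 12 of cell markers of kidney and blood), together with the complement lists joined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 34 lists per comparison. Camera at the preset correlation treats list members as nearly independent, and at the estimated correlation most calls were lost, as given beside each. Named genes followed a rule also fixed before: in each main comparison the 6 highest and 6 lowest log2 fold changes among called genes, up to 12 called complement genes by lowest p, and the 2 members of lowest p of every other list called by camera; for the interaction and time results the 4 of lowest adjusted p. Members named beyond that, such as C1QA, SERPING1, CR1 and HP at baseline, C3, C1R, CFB and FCN3 in the later donor comparison, C1S in deceased-donor kidneys, C2 in test set 1 and the complement genes of the interaction, complete a list's count and were chosen after their values were seen. Genes marked as log2 fold changes carry a standard error from the moderated variance.

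The mean of the complement list per biopsy and the degradation measures (3' minus 5' control probe sets of GAPDH and ACTB, and the deposited array median) were compared by permutation tests with 100000 resamples, two-sided. Comparisons that share baseline biopsies were set beside 100 simulated draws of unchanged groups made from residuals. The calling procedure was tested on simulated data with known changes. For the baseline comparison with 16181 genes it recovered 34.3% of genes changed by 0.5 on the log2 scale, 76.1% by 1 and 98.5% by 2. For the post-transplant donor comparison it recovered 40.3%, 80.6% and 100%, and for test set 1 0%, 17.9% and 69.7%. In each simulation 67, 67 and 66 genes were changed by these sizes, and genes varied independently of each other. Real genes vary together and other numbers may change, so these shares need not hold for the real comparisons.

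Alternatives were the deposited scale, no filter or a filter at the median level, averaged probe sets, all probe sets, trend and robust variance, and array weights. Further ones were a degradation covariate, no set or time covariate, all 95 arrays in 1 fit, and single time points. The rest were leaving out biopsies of test set 1 in turn, a linear trend over the time points taken as equal steps, and a fold of at least 1.5. The permutation test of the complement mean, the counts of biopsies lying in a direction and the look at baseline calls in later biopsies were also added after seeing the data. After seeing the data, 2 alternatives were added: leaving out 5 arrays that stood apart from the others in correlation (mean under 0.877, median of all 0.916), and the macrophage marker mean as a covariate. The software was R 4.3.3 with limma 3.58.1 and the R package data.table, version 1.17.8, and matplotlib for the plots.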

Results

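Gene expression was measured in 95 kidney allograft biopsies, each on its own whole-genome oligonucleotide array. At baseline, when the kidney had been placed but its blood flow had not yet been restored, there were 14 biopsies of kidneys from deceased donors and 14 of kidneys from living donors. The baseline biopsies were divided by their labels into a training set of 9 and 9 and a test set 1 of 5 and 5. The other 67 biopsies were taken after transplantation. Of these, 55 were of living-donor kidneys (14 at 3 months, 13 at 6, 15 at 12 and 13 at 24) and 12 of deceased-donor kidneys (3 at 3 months, 3 at 6, 4 at 12 and 2 at 24). After quantile normalization 16181 genes entered each test. Levels are log2 values, and the number of arrays limits the precision of each comparison. No detection calls came with the values. A fold is uncertain where the mean of a group lay under 3.12, the mean level below which probe sets were left out as dim. That level is a percentile and not a detection limit, so folds against means not far above it are uncertain too. Among these were the living-donor baseline means of C1QB (3.19), VSIG4 (3.69) and C2 (3.81). The labels do not tie biopsies to persons, so some biopsies may come from the same person. The p-values measure only the spread between these biopsies and may be too small.

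The first comparison asked how kidneys from deceased and living donors differed at implantation, in particular in the genes of complement, the protein cascade of innate immunity that marks and lyses cells. Of 37 complement genes measured, 14 were higher in deceased-donor biopsies, 1 was lower and the others did not pass the test. C3, the component on which all activation routes converge, was 7.09-fold higher (95% interval 3.83 to 13.1), with a log2 level of 7.81 ± 1.44 (SD, n = 14) against 4.98 ± 0.93 (SD, n = 14). C2, the protease of the classical and lectin pathways, was 5.46-fold higher, and CFB, factor B of the alternative pathway, 4.40-fold higher. The limma adjusted p was 0.000223 for C3, 9.12e-05 for C2 and 3.96e-05 for CFB. C3 and CFB lay above the living-donor mean in 14 of 14 deceased-donor biopsies, and C2 in 13 of 14.

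In the list of the classical and lectin pathways, 7 of 11 measured genes were higher in deceased-donor biopsies and none was lower, with a mean log2 difference of 1.03. They were C1QB (3.70-fold), C1QC (2.12-fold) and C1QA (1.79-fold), which encode the chains of the recognition molecule C1q, the C1 proteases C1R (3.54-fold) and C1S (3.55-fold), the lectin FCN3 (4.01-fold) and C2. The list was called by camera with an adjusted p of 2.32e-07, and it was the only list of this comparison that also passed with an estimated correlation (adjusted p = 0.044). Both called members of the 3 measured in the alternative pathway list were higher, namely C3 and CFB (list mean 1.74, camera adjusted p = 0.000615, and 0.082 with an estimated correlation). Of the terminal components, C6 was 3.05-fold higher, and 1 of 5 measured members passed. Among the regulators, CFI (1.5-fold) and SERPING1 (1.63-fold), the inhibitor of the C1 proteases, were higher, whereas CR1, a receptor that restrains C3 activation, was 2.01-fold lower with an adjusted p of 0.0295. VSIG4, a macrophage receptor for C3 fragments, was 4.86-fold higher. Camera did not call the lists of terminal components (adjusted p = 0.497), regulators (0.182) and receptors (0.182). ITGB2, the shared chain of the leukocyte complement receptors, was 1.96-fold higher, a call that was lost when the probe sets of the gene were averaged (adjusted p = 0.0975) or when all 95 arrays entered the fit (adjusted p = 0.0925).

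Over all 37 complement genes the mean log2 difference was 0.63 (camera adjusted p = 5.64e-08, and 0.082 with an estimated correlation). Adjusted over the list alone, 17 genes were higher and 2 lower. The mean of the list in each biopsy was 6.50 ± 0.35 (SD, n = 14) in deceased-donor kidneys and 5.87 ± 0.20 (SD, n = 14) in living-donor kidneys. It lay above the living-donor mean in 14 of 14 deceased-donor biopsies (two-sided permutation test, p = 2e-05, adjusted p = 8e-05 over 4 comparisons). Markers of macrophages and monocytes moved with these genes, with 5 of 12 higher and 1 lower (mean 0.42, camera adjusted p = 0.0188, and 0.612 with an estimated correlation). CD163, a scavenger receptor of macrophages, was 4.65-fold higher, and AIF1 was 2.03-fold lower.

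**Figure D1:**
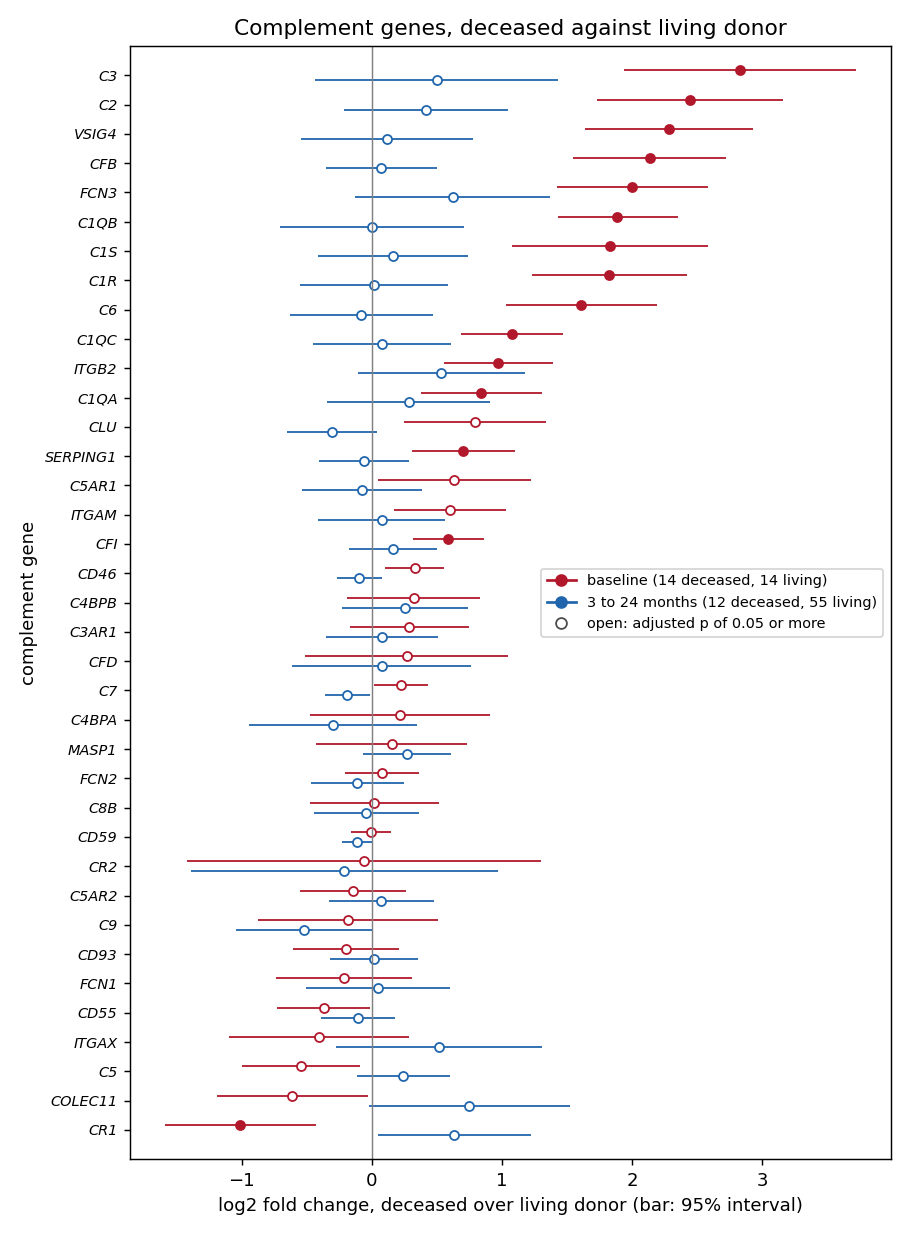
Log2 fold change of each of the 37 measured complement genes, deceased over living donor, at baseline (red, 14 against 14 biopsies) and at 3 to 24 months (blue, 12 against 55). Bars are 95% intervals and filled points have a limma adjusted p under 0.05. At baseline 14 genes were higher and 1 lower, and after transplantation none passed.

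In total 1096 genes differed at baseline between the donor types, 627 higher and 469 lower in deceased-donor biopsies (limma, Benjamini-Hochberg adjusted p under 0.05), and 664 of them by at least 1.5-fold, where the balance turned to 311 higher and 353 lower. In the values as deposited 849 were higher and 437 lower. The gene with the highest fold was SERPINA3, an acute-phase protease inhibitor, at 19.1-fold (95% interval 8.73 to 41.8), followed by LTF, the iron-binding protein lactoferrin, at 11.4-fold. RARRES1 was 5.36-fold and REG1A, a secreted protein of regenerating epithelium, 5.27-fold higher, against a dim living-donor mean of 3.11. At the other end, SOST, a secreted inhibitor of Wnt signalling, was 6.97-fold lower. RNF212B was 6.62-fold, ADGRV1 6.14-fold, SERPINA6, the cortisol-binding globulin, 5.31-fold, APOC3 4.55-fold and NECAB2 4.37-fold lower. Each of these lower genes lay under the living-donor mean in 14 of 14 deceased-donor biopsies.

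Beyond complement, 3 of 12 acute-phase genes were higher, namely SERPINA3, LTF and HP (list mean 0.98, camera adjusted p = 0.0231, and 0.506 with an estimated correlation). Metallothioneins, which bind zinc and copper, went the other way. MT1F was 2.14-fold and MT1E 1.87-fold lower, 6 of the 7 measured members were lower, and the mean was -0.91 (camera adjusted p = 5.64e-08, and 0.0962 with an estimated correlation). The probe sets of MT1F and MT1E may also read related sequences. Members of this list may therefore not be separate measurements, here and in the later comparisons. In the unfolded protein response list 3 of 10 were higher, among them HSPA5, the chaperone of the endoplasmic reticulum, at 1.92-fold and PDIA4 at 1.36-fold (camera adjusted p = 0.00444, and 0.082 with an estimated correlation). In the proliferation list 3 of 14 were higher, with BIRC5 at 2.18-fold and AURKA at 2.03-fold (camera adjusted p = 0.00598, and 0.277 with an estimated correlation). The NRF2 antioxidant list had 3 of 9 higher, including SLC7A11 at 1.74-fold and NQO1 at 1.61-fold (camera adjusted p = 0.0331, and 0.444 with an estimated correlation). The oxidative phosphorylation list had 2 of 22 higher, NDUFS1 at 1.48-fold and COX5A at 1.29-fold (camera adjusted p = 0.0135, and 0.684 with an estimated correlation). The living-donor mean of SLC7A11 was dim, at 2.97. The calls of SLC7A11, NDUFS1 and COX5A were lost when probe sets of a gene were averaged, and that of NQO1 when all 95 arrays entered the fit (adjusted p = 0.0559). Adjusted over the list alone, 5 acute-phase, 4 unfolded protein response, 4 proliferation, 3 NRF2, 2 oxidative phosphorylation and 5 macrophage genes were higher, and 6 metallothioneins and 1 macrophage gene were lower. No list of tubule, podocyte, endothelial, smooth muscle, lymphocyte, neutrophil, red cell or platelet markers passed camera at baseline, and the same held for the lists of tubular injury, NF-kB cytokines, immediate early genes, hypoxia, heat shock, interferon gamma response, MHC class II, extracellular matrix, glucocorticoid response and fatty acid oxidation, of which extracellular matrix had the smallest adjusted p, 0.0602. Of the 10 lists called by camera at baseline, 7 also passed fry, which asks whether a list moved one way without comparing it with other genes. Acute-phase genes (fry adjusted p = 0.0546), macrophage markers (0.0719) and oxidative phosphorylation (0.145) did not pass it. Complement regulators (0.0145, mean 0.174) and B and plasma cell markers (0.0208, mean -0.335) passed fry alone, in opposite directions. The degradation measure of the GAPDH control probe sets (3' minus 5' end) was 1.44 ± 0.50 (SD, n = 14) in deceased-donor and 1.54 ± 0.65 (SD, n = 14) in living-donor biopsies (permutation test, adjusted p = 0.725 over 12 tests).

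The training set and test set 1 allowed the donor difference to be looked at in separate biopsies. In the training set 793 genes differed, 393 higher and 400 lower, of which 12 complement genes were higher and 1 lower. In the values as deposited the training set gave 577 higher and 326 lower, so the share of higher calls was 63.9% there and 49.6% after quantile normalization. In test set 1 a single gene passed limma after adjustment. It was C2 (adjusted p = 0.0291), a call that was lost with the GAPDH degradation measure as a covariate and depended on single biopsies: it was lost without any 1 of living-donor replicates 11, 12, 13 and 14 or deceased-donor replicates 10, 12, 13 and 14. In test set 1, 1134 genes had an unadjusted p under 0.05. Of the 793 training calls, 664 had the same sign in test set 1 (83.7%, against 61.4% of all genes). When only these 793 genes were tested there, 32 passed with the same sign (limma, adjusted over these genes). At an unadjusted p under 0.05, 183 had the same sign and 1 the opposite sign. The mean log2 difference of the complement list was 0.61 in the training set and 0.66 in test set 1 (camera adjusted p = 4.88e-06 and 8.73e-06, and 0.142 and 0.313 with an estimated correlation). In test set 1 no list passed fry, where the complement list had an adjusted p of 0.0864. Adjusted over the list alone, 16 complement genes were higher and 2 lower in the training set, and 11 and 1 in test set 1. The 32 repeated calls depended on single biopsies of test set 1: without living-donor baseline replicate 10 there were 65, without replicates 11 and 12 there were 20 and 13, and without deceased-donor baseline replicates 10 and 12 there were 20 and 17.

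The second comparison asked whether the donor types still differed after transplantation. With 12 deceased-donor and 55 living-donor biopsies, and time as a covariate, no gene passed limma (920 at an unadjusted p under 0.05, smallest adjusted p 0.823). C3 was 6.55 ± 1.23 (SD, n = 12) in deceased-donor and 6.04 ± 1.52 (SD, n = 55) in living-donor kidneys, a log2 difference of 0.50 with a fold interval of 0.741 to 2.69. CFB differed by 0.07 (fold interval 0.785 to 1.41) and C1R by 0.02 (0.683 to 1.5). Among the 37 complement genes the smallest adjusted p was 0.843, and 3 had an unadjusted p under 0.05. The mean of the complement list was 6.33 ± 0.37 (SD, n = 12) and 6.22 ± 0.32 (SD, n = 55), with a permutation p of 0.33. The upper bounds of the intervals of C3 and FCN3 still allowed differences of 2.69-fold and 2.59-fold. The highest upper bound of the 37 genes was that of COLEC11, at 2.87-fold.

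Several lists were called by camera in this post-transplant comparison although none of their members passed alone. Proximal tubule markers were above 0 in 19 of 19 genes (mean 0.57), with SLC6A19 at 1.02 ± 0.42 (SE) and SLC5A2 at 0.82. Thick ascending limb markers were below 0 in all 6 genes (mean -0.50), with KCNJ1 at -0.42 and SLC12A1 at -0.34. Adjusted over the list alone, 4 of the 6 were lower, and no member of the other lists in this paragraph passed. T and NK cell markers averaged 0.48, with CD2 at 0.92 and GNLY at 0.55. Podocyte markers averaged 0.36, with WT1 at 0.61 and NPHS1 at 0.59. The interferon gamma list averaged 0.28, with WARS1 at 0.30 and CXCL9 at 0.80. Metallothioneins averaged 0.26, with MT1F at 0.31 and MT2A at 0.33. Immediate early genes averaged -0.19, with IER3 at -0.31 and JUN at -0.41. The camera adjusted p ranged from 7.85e-06 for proximal tubule to 0.0485 for immediate early genes. With an estimated correlation none of these lists passed, the smallest adjusted p being 0.457, for the thick ascending limb, and none passed fry (smallest adjusted p 0.322). In the balanced test set 2 (9 and 9 biopsies) no gene passed limma either (333 at an unadjusted p under 0.05), and the complement list averaged 0.18 (camera adjusted p = 0.0806, and 0.0445 with the GAPDH degradation measure as a covariate). Camera called 5 lists there, complement receptors among them (adjusted p = 0.00602, and 0.617 with an estimated correlation), and none passed fry (smallest adjusted p 0.823).

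The third comparison set living-donor biopsies after transplantation against living-donor biopsies at baseline. The largest falls were in immediate early genes, the transcription factors and feedback regulators that cells switch on within minutes of a stimulus. All 18 measured members fell, by 2.15 on average on the log2 scale (camera adjusted p = 5.24e-31, and 0.00251 with an estimated correlation). FOSB fell 30.2-fold, from 9.58 ± 1.40 (SD, n = 14) to 4.66 ± 1.86 (SD, n = 55), NR4A3 fell 13-fold, FOS 12.8-fold, NR4A1 9.78-fold and ZFP36, which destabilizes cytokine messages, 8.09-fold. FOSB and NR4A3 were under the baseline mean in 54 of 55 later biopsies. MAFF and the antisense transcript BABAM2-AS1 each fell 8.20-fold; the array cannot always separate an antisense transcript from overlapping sequence. Of 7 measured glucocorticoid-responsive genes, 6 fell, with ERRFI1 4.05-fold and the kinase gene SGK1 1.89-fold lower (camera adjusted p = 2.82e-11, and 0.00229 with an estimated correlation). In the NF-kB cytokine list 6 of 17 fell and 1 rose, with IL6 5.04-fold, to a dim mean of 3.11, and CXCL8 3.84-fold lower (camera adjusted p = 7.57e-05, and 0.176 with an estimated correlation). Within the lists, 18 immediate early genes, 6 glucocorticoid-responsive genes and 10 NF-kB cytokine genes fell and 1 of the last rose, adjusted over the list alone.

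Genes of connective tissue and of immune cells rose in these living-donor grafts. Of 18 extracellular matrix genes 14 rose, with a mean of 1.06 (camera adjusted p = 1.11e-14, and 0.051 with an estimated correlation), including the collagen genes COL3A1 (4.02-fold, 95% interval 3.07 to 5.25) and COL6A3 (2.90-fold). In the MHC class II list 7 of 8 rose, with HLA-DMB at 2.58-fold and the invariant chain CD74 at 1.58-fold (camera adjusted p = 2.48e-08, and 0.051 with an estimated correlation). T and NK cell markers rose in 10 of 14, with NKG7 at 3.27-fold (from a dim 2.39) and GZMA at 3.21-fold (camera adjusted p = 2e-06, and 0.149 with an estimated correlation). Interferon gamma genes rose in 9 of 15, with the immunoproteasome subunits PSMB8 at 1.99-fold and PSMB10 at 1.84-fold (camera adjusted p = 5.84e-06, and 0.161 with an estimated correlation). B and plasma cell markers rose in 6 of 9, with IGKC at 4.54-fold and TNFRSF17 at 2.43-fold (camera adjusted p = 0.00223, and 0.145 with an estimated correlation). Macrophage markers rose in 9 of 12, with MS4A6A at 3.38-fold and CSF1R at 1.91-fold (camera adjusted p = 2.61e-05, and 0.176 with an estimated correlation). Here 16 matrix, 7 MHC class II, 11 T and NK cell, 11 interferon gamma, 6 B and plasma cell and 9 macrophage genes rose, adjusted over the list alone. The genes with the highest folds were LTF (8.37-fold), IGLJ3 (7.62-fold), CCL21, a chemokine that draws lymphocytes and dendritic cells (6.44-fold), IGLL5 (5.69-fold) and IGLV1-44 (5.12-fold). An immunoglobulin kappa orphon segment was 5.94-fold higher. The immunoglobulin segments share sequence, so which of them was measured is uncertain.

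Of the complement genes, 12 rose and 1 fell in living-donor kidneys after transplantation (13 and 2 adjusted over the list alone). C1S was 3.01-fold, C1QB 2.74-fold, ITGB2 2.62-fold, C1QA 2.56-fold, C1R 2.43-fold, VSIG4 2.28-fold and C1QC 2.02-fold above baseline. CFB (1.73-fold), SERPING1 (1.70-fold), CLU (1.66-fold) and C7 (1.39-fold) rose less. CD55, which speeds the decay of C3 convertases on cell surfaces, fell 1.47-fold, a call that was lost when its probe sets were averaged (adjusted p = 0.219). The complement mean rose by 0.35, in 45 of 55 biopsies above the baseline mean (permutation p = 0.00018, adjusted p = 0.00036), with a camera adjusted p of 0.00397 and an adjusted p of 0.176 with an estimated correlation. The lists of the classical and lectin pathways (5 of 11 rose) and of the alternative pathway (1 of 3 rose) were also called by camera, with adjusted p = 0.149 and 0.176 with an estimated correlation, and the other 3 complement lists were not (smallest camera adjusted p 0.249). With the macrophage marker mean as a covariate the rise was 0.11 ± 0.07 (SE) and no longer passed (camera adjusted p = 0.208).

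Further lists were called by camera in living-donor grafts. Metallothioneins fell in 5 of 7 (MT1M 2.18-fold, MT2A 1.55-fold), NRF2 targets in 5 of 9 (GCLM 1.79-fold, SRXN1 1.59-fold), heat shock genes in 2 of 12 (BAG3 2.23-fold, HSPD1 1.28-fold) and hypoxia genes in 4 of 17 with 1 rise (ADM 1.99-fold, P4HA1 1.42-fold lower). In the proliferation list 5 of 14 rose (BIRC5 2.19-fold, RRM2 1.63-fold). Among nephron markers, the thick ascending limb list had 3 of 6 higher (CASR 2.29-fold, KCNJ1 1.41-fold), the distal nephron list 3 of 18 lower and 1 higher (TRPM6 6.21-fold and ATP6V0D2 1.66-fold lower) and the podocyte list 1 of 8 lower (NPHS1 1.93-fold, with PLA2R1 at -0.78 without passing). No proximal tubule gene passed alone although all 19 lay below 0 (mean -0.63), with SLC5A2 at -0.87 and SLC22A8 at -1.45 (adjusted p = 0.0895 and 0.0989). Oxidative phosphorylation (NDUFS1 and NDUFV1 lower) and fatty acid oxidation (ACADVL lower, PPARA at -0.36 without passing) were also called by camera. With an estimated correlation none of the lists in this paragraph passed, with adjusted p between 0.118 and 0.555. In these lists 7 metallothioneins, 6 NRF2 targets, 2 heat shock, 4 hypoxia, 3 distal nephron, 1 podocyte and 1 oxidative phosphorylation gene fell, and 6 proliferation, 5 thick ascending limb, 1 distal nephron and 1 hypoxia gene rose, adjusted over the list alone. Calls of HSPD1, NDUFV1 and KCNJ1 were lost with averaged probe sets, and that of NDUFV1 also with no filter on dim probe sets and with array weights. With array weights PPARA, SLC5A2, SLC22A8 and PLA2R1 passed, and PLA2R1 also with averaged probe sets and at 12 months alone. Of the 23 lists called in living-donor grafts 20 also passed fry, while oxidative phosphorylation (adjusted p = 0.179), proximal tubule (0.1) and distal nephron (0.0979) did not. Smooth muscle markers passed fry alone (0.0204, mean 0.356).

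In total 2890 genes changed in living-donor kidneys, 1694 higher and 1196 lower after transplantation, and 1550 by at least 1.5-fold. Each time point alone against baseline gave 1287 calls at 3 months, 1428 at 6, 2082 at 12 and 1295 at 24, with fewer biopsies per test. With averaged probe sets the balance of living-donor calls turned to 1505 higher and 1618 lower. The deposited array median was higher after transplantation, 4.38 ± 0.13 (SD, n = 55) against 4.29 ± 0.08 (SD, n = 14), with a permutation adjusted p of 0.0547.

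**Figure D2:**
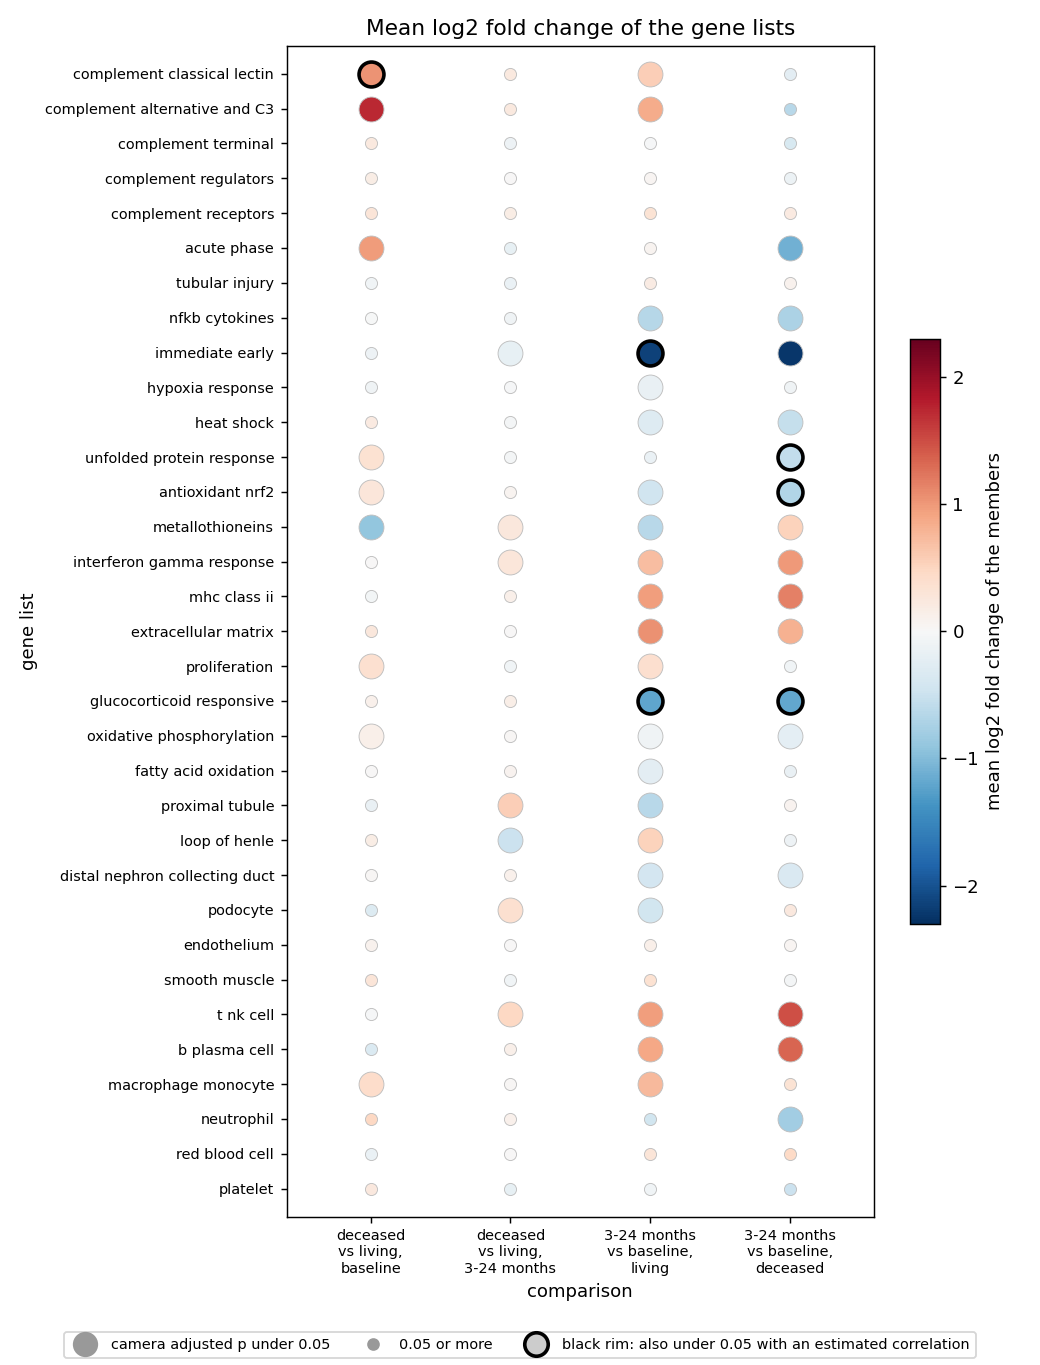
Mean log2 fold change (colour) of each gene list in 4 comparisons: deceased against living donor at baseline and at 3 to 24 months, and 3 to 24 months against baseline in each donor type. Large points have a camera adjusted p under 0.05, and a black rim marks lists that also passed with an estimated correlation. Immediate early genes fell by 2.15 in living-donor and by 2.23 in deceased-donor grafts.

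The fourth comparison set the 12 later deceased-donor biopsies against the 14 at baseline. The fall of the immediate early genes was seen here too, in 16 of 18 members with a mean of -2.23 (camera adjusted p = 3.2e-15, and 0.111 with an estimated correlation). FOSB fell 19.0-fold, NR4A1 18.3-fold, FOS 14.9-fold, DUSP1 13.7-fold and ATF3 11.6-fold. SERPINA3, the highest of the baseline donor differences, fell 30.3-fold (95% interval of the ratio 0.0171 to 0.0635), from 9.5 ± 1.22 (SD, n = 14) to 4.58 ± 1.27 (SD, n = 12). With SERPINA1 (3.15-fold lower), 4 of 12 acute-phase genes fell (camera adjusted p = 0.00631, and 0.329 with an estimated correlation). All 7 glucocorticoid-responsive genes fell, with FKBP5 5.79-fold and ZBTB16 2.77-fold lower (camera adjusted p = 1.06e-08, and 0.0116 with an estimated correlation). In the unfolded protein response list 4 of 10 fell, with HYOU1 3.01-fold and HSPA5 2.07-fold lower (camera adjusted p = 1.86e-05, and 0.0107 with an estimated correlation). NRF2 targets fell in 6 of 9, with SRXN1 2.48-fold and TXNRD1 1.75-fold lower (camera adjusted p = 8.28e-07, and 0.0155 with an estimated correlation). In total 17 immediate early, 4 acute-phase, 7 glucocorticoid-responsive, 7 unfolded protein response and 6 NRF2 genes fell, and 1 acute-phase gene rose, adjusted over the list alone.

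Among the called genes with the highest rises in deceased-donor grafts, CD52 rose 11.8-fold, the Fc receptor-like gene FCRL1 9.01-fold and the chemokine CCL19 8.97-fold. SIT1 rose 8.85-fold and TRBC1, the constant part of the T cell receptor beta chain, 8.09-fold. IGLJ3 rose 13.9-fold, with the same uncertainty of sequence as above. The baseline means of FCRL1 (2.33), SIT1 (2.56), IGLJ3 (2.79) and CXCL11 (2.61), and the later mean of FPR1 (2.78), were under the dim level of 3.12 and not shown to lie above background, so the folds of these 5 genes are uncertain. Of 14 T and NK cell markers 12 rose, with GZMK at 5.97-fold and CD2 at 3.86-fold (camera adjusted p = 1.23e-08, and 0.111 with an estimated correlation). B and plasma cell markers rose in 6 of 9, with JCHAIN at 7.47-fold and MS4A1 at 5.90-fold (camera adjusted p = 0.000188, and 0.0964 with an estimated correlation). MHC class II genes rose in 6 of 8 (HLA-DPB1 3.96-fold, HLA-DMB 3.03-fold), interferon gamma genes in 6 of 15 (CXCL9 7.35-fold, CXCL11 5.51-fold), matrix genes in 7 of 18 (VCAN 3.71-fold, LUM 2.15-fold) and metallothioneins in 5 of 7 (MT1F 1.90-fold, MT1G 1.75-fold). Heat shock genes fell in 5 of 12 (BAG3 2.50-fold, CRYAB 2.42-fold), NF-kB cytokines in 6 of 17 with 1 rise (CXCL8 3.90-fold, SOCS3 2.73-fold lower), oxidative phosphorylation genes in 5 of 22 (NDUFS1 1.66-fold, COX5A 1.34-fold), distal nephron markers in 4 of 18 (TRPM6 2.70-fold, SCNN1A 2.23-fold) and neutrophil markers in 2 of 6 (S100A8 4.61-fold, FPR1 2.92-fold). These lists were called by camera with adjusted p up to 0.0286, and none of the lists in the last 2 sentences passed with an estimated correlation (adjusted p between 0.126 and 0.533). Across these lists 13 T and NK cell, 7 B and plasma cell, 6 MHC class II, 10 interferon gamma, 9 matrix and 6 metallothionein genes rose, and 5 heat shock, 8 NF-kB cytokine, 5 oxidative phosphorylation, 5 distal nephron and 3 neutrophil genes fell, adjusted over the list alone. In the opposite direction, 1 T and NK cell, 1 B and plasma cell and 1 NF-kB cytokine gene passed. The calls of CXCL8 and SCNN1A were lost with averaged probe sets, and that of TRPM6 with all 95 arrays in the fit. Of the 16 lists called in deceased-donor grafts 14 also passed fry, while NF-kB cytokines (adjusted p = 0.115) and distal nephron (0.148) did not. Complement regulators (0.0135, mean -0.133), hypoxia genes (0.0135, mean -0.0949), red cell markers (0.0202, mean 0.454) and the 2 platelet markers (0.019, mean -0.492) passed fry alone.

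Complement genes went in both directions in the deceased-donor kidneys, with 8 lower and 3 higher after transplantation (8 and 4 adjusted over the list alone). FCN3 fell 4.69-fold, C6 4.25-fold, C2 2.71-fold, CFB 2.39-fold, C5AR1, the receptor of the fragment C5a, 2.18-fold, VSIG4 2.00-fold, CFI 1.45-fold and CD46 1.39-fold. ITGAX rose 3.02-fold, CR1 1.93-fold and C5 1.61-fold. C1S did not pass, at 7.65 ± 1.04 (SD, n = 14) before and 7.59 ± 1.04 (SD, n = 12) after. The list mean changed by -0.17, a difference that did not pass (permutation p = 0.23, camera adjusted p = 0.129). With the macrophage marker mean as a covariate it was -0.32 ± 0.10 (SE), with a camera adjusted p of 0.00226. The weakest of these calls were lost under other settings: VSIG4 with the values as deposited (adjusted p = 0.069), without the filter on dim probe sets (0.0559), with the GAPDH covariate (0.0511) and with all 95 arrays in the fit (0.0664), C5 without the filter (0.0523), CD46 with averaged probe sets (0.0656), and CR1 with averaged probe sets (0.32), with array weights (0.0806) and without the arrays that stood apart (0.0609). In total 2595 genes changed, 1384 higher and 1211 lower, and 1662 by at least 1.5-fold. The balance depended on the processing, with 1746 higher and 1153 lower in the values as deposited and 1158 higher and 1503 lower with averaged probe sets. The deposited array median was 4.41 ± 0.14 (SD, n = 12) after and 4.25 ± 0.14 (SD, n = 14) before transplantation (permutation adjusted p = 0.036).

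**Figure D3:**
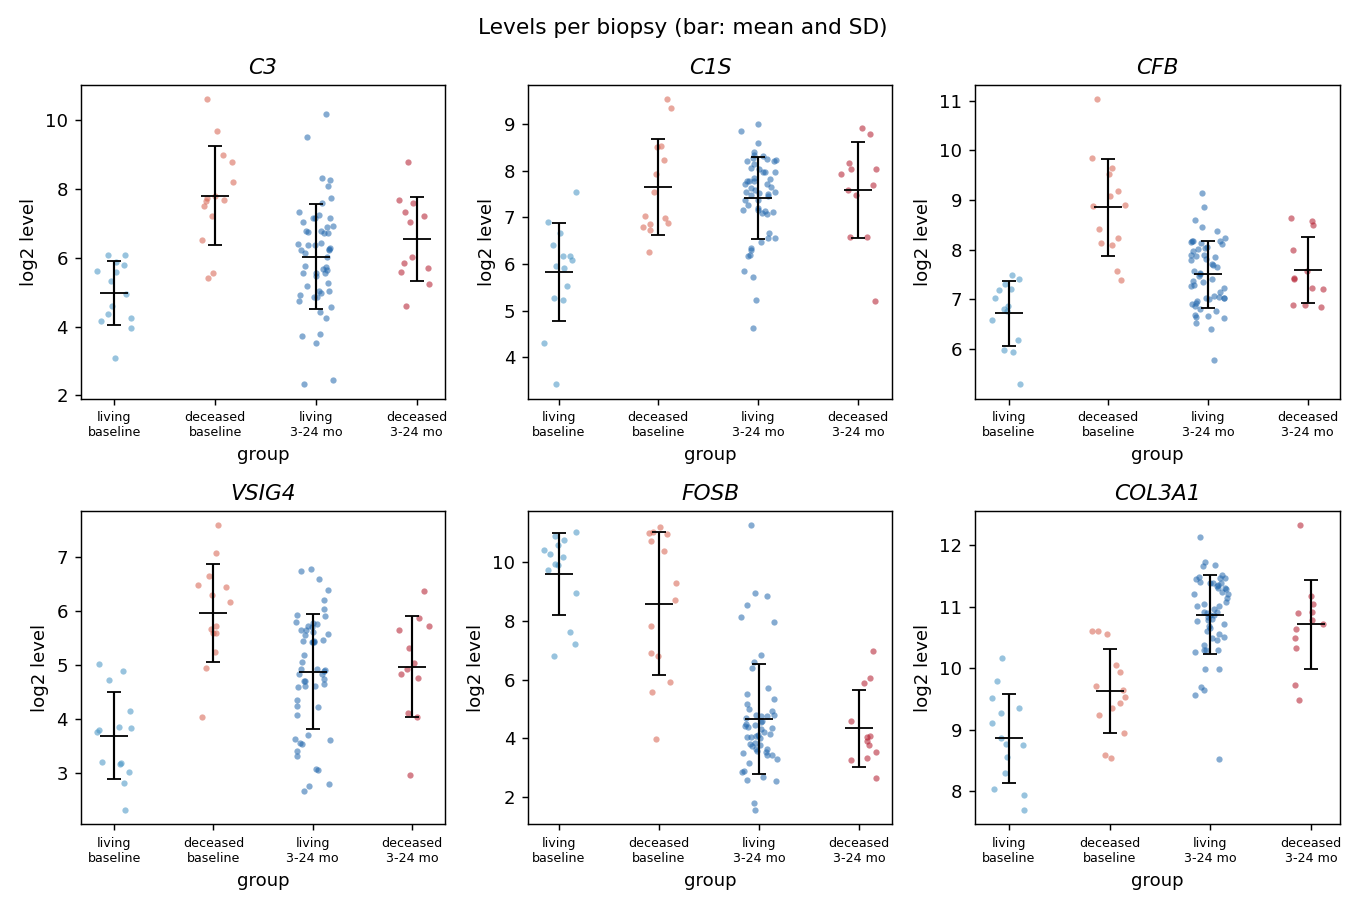
Log2 level of 6 genes in each biopsy (points), with the mean and SD of each group (black), by donor type and phase: 14, 14, 55 and 12 biopsies from left to right. C3, C1S, CFB and VSIG4 were lowest on average in living-donor baseline biopsies, FOSB was lower and COL3A1 higher in both groups taken after transplantation.

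Whether the change after transplantation differed between the donor types was tested directly, with all 95 biopsies in 1 model. The change differed for 284 genes, 114 with a more positive and 170 with a more negative change in deceased-donor kidneys (limma). The 4 with the lowest adjusted p were CNR1, the cannabinoid receptor 1 (difference of log2 changes -2.08 ± 0.32, SE), CTSF (1.40 ± 0.22), WIF1, an inhibitor of Wnt signalling (1.92 ± 0.31), and ETV5 (1.29 ± 0.22). CNR1 went from 4.79 ± 0.98 (SD, n = 14) to 2.93 ± 0.62 (SD, n = 12) in deceased-donor kidneys and from 2.85 ± 0.66 (SD, n = 14) to 3.07 ± 0.56 (SD, n = 55) in living-donor kidneys. The last 3 of the 4 means were under the dim level of 3.12 and not shown to lie above background, so the size of this difference is uncertain. Of the complement genes, 8 had a more negative and 1 a more positive change in deceased-donor kidneys (list mean -0.53, camera adjusted p = 1.93e-05, and 0.0739 with an estimated correlation). Of the list, 14 were more negative and 3 more positive, adjusted over the list alone. The 9 called over all genes were VSIG4 (-2.19), CFB (-2.04), C2 (-2.01), C1QB (-1.88), C1R (-1.80), C6 (-1.69), C1S (-1.66) and CLU (-1.09), against CR1 (1.63). Each such value is the later donor difference less the baseline donor difference, so it is not separate from the baseline comparison. For CFB the log2 donor difference was 2.14 at baseline and 0.07 later. The call of ETV5 was lost with averaged probe sets (adjusted p = 0.0803). Of 12 lists called for the interaction 7 also passed fry.

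The post-transplant changes of the donor types were measured in separate biopsies. Of the genes called in each, 572 rose in both and 377 fell in both, where independent lists would share 145 and 89.5, and 27 went in opposite directions against 229. Across genes, which are not independent replicates, the correlation of the log2 changes was 0.551. Of the 1096 genes that differed at baseline, 480 (43.8%) kept their sign between donor types after transplantation, against 48.3% of all genes, and none passed when adjusted over these genes alone (limma, 21 with the same and 52 with the opposite sign at an unadjusted p under 0.05).

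The baseline donor difference and the post-transplant change of living-donor kidneys share the 14 living-donor baseline biopsies. Their log2 fold changes had a correlation of 0.244 across genes and a covariance of 0.0364. Unchanged groups simulated against the same controls gave a mean correlation of 0.619 (0.271 to 0.862 in 100 draws) and a covariance of 0.0256, so the covariance exceeded the simulated one by 0.0108. With the controls split into 7 and 7 the correlation averaged 0.0677 (-0.11 to 0.276). Of the genes called in both, 156 were higher in both and 115 lower in both, against 65.6 and 34.7 for independent lists, and 15 and 17 went opposite ways, against 46.3 and 49.1. Independent lists leave out the shared biopsies, and the simulated unchanged groups, which leave out real effects, had no gene called in both. With split controls, no set covariate and fewer calls the counts averaged 28.4 and 16.3 in the same direction, against 11.8 and 6.11 for independent lists, and 4.99 and 7.45 in opposite directions, against 8.90 and 8.54. For the change in deceased-donor kidneys, which shares the 14 deceased-donor baseline biopsies, the correlation was -0.556 and the covariance -0.094. The simulated values were -0.444 (-0.846 to 0.0448) and -0.0262, a difference in covariance of -0.0678, and split controls gave -0.384 (-0.486 to -0.213). Of the genes higher at baseline 316 fell and 2 rose after transplantation, against 46.9 and 53.6 for independent lists, and of the genes lower at baseline 210 rose and 7 fell, against 40.1 and 35.1. Here the shared biopsies alone favour opposite signs, which independent lists leave out, and the simulated unchanged groups again had no gene called in both. With split controls in the same way, of the genes higher at baseline 34.8 fell and 0.13 rose on average, against 3.26 and 3.05, and of the lower ones 25.9 rose and 0.86 fell, against 2.75 and 2.99.

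Within the 55 later living-donor biopsies, no gene changed with time by limma's F test over 3, 6, 12 and 24 months (890 at an unadjusted p under 0.05, smallest adjusted p 0.743), nor between 24 and 3 months (545, smallest adjusted p 0.236). ADAMTS1, a secreted protease that cleaves matrix proteoglycans, had the lowest p in both, at 6.40 ± 0.76 (SD, n = 13) at 24 months and 7.86 ± 0.65 (SD, n = 14) at 3 months (adjusted p = 0.236). It passed with a linear trend over time (adjusted p = 0.0314) and with the GAPDH degradation measure as a covariate (adjusted p = 0.0421). The next lowest were ADAM28 at 1.03, IL27RA at -0.91 and GSTCD-AS1 at 1.16 in the comparison of 24 with 3 months (the last 2 each with a dim group mean, 3.07 and 2.83), and TBC1D32, IGFBP6 and GNAO1-DT in the F test (adjusted p = 0.804), where IGFBP6 passed with array weights (adjusted p = 0.0458). The complement list averaged 0.13 between 24 and 3 months (camera adjusted p = 0.047, and 0.445 with an estimated correlation), with no member passing alone. Its camera call was lost with no filter on dim probe sets (adjusted p = 0.222), a filter at the median level (0.11), averaged probe sets (0.0715) and the GAPDH covariate (0.0741), and over the alternatives the mean ran from 0.08 to 0.22. Camera also called 13 other lists between these times with no member passing, among them T and NK cell markers (mean 0.54, adjusted p = 1.98e-06), immediate early genes (-0.47, 5.84e-05) and proximal tubule markers (0.53, 9.3e-05), and with an estimated correlation none passed (smallest adjusted p 0.425), nor did any pass fry (0.529).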

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

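The test on handling of the baseline biopsies was chosen after its result was seen. The macrophage covariate was added after the complement difference had been seen but before its own value was, and the other tests in this part were chosen before their results were seen. The random splits were drawn again after a first draw had been seen, to remove repeated splits, and the counts given are from the second draw unless the first is named.

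The 37 complement genes averaged 0.63 higher on the log2 scale in deceased-donor kidneys at baseline. Most of them did not pass alone, and the camera call of the list was lost with an estimated correlation. If more macrophages were the whole cause, the shift was predicted to be lost with the macrophage marker mean as a covariate. In the 26 members outside 11 genes best known from leukocytes it went from 0.594 to 0.479 ± 0.11 (SE), and over all members to 0.477. The markers did not all move together, with CD163 4.65-fold higher and AIF1 2.03-fold lower, so their mean measures macrophages only roughly. A rough measure leaves part of such an effect in place, so the fit cannot decide whether more macrophages were the whole cause. The GAPDH degradation measure hardly differed between the groups, at 1.44 in deceased-donor and 1.54 in living-donor biopsies. No difference in degradation was thus seen by this measure. The ACTB measure was 4.73 in deceased-donor and 4.99 in living-donor biopsies (permutation test, adjusted p = 0.725). In both groups the ACTB signal was thus much lower at the 5' end than at the 3' end. As a covariate the GAPDH measure could hardly move the shift of all members, which was 0.639 ± 0.109 (SE), so that fit does not decide on degradation. The donor type named by the labels, with all that differs between deceased and living donation, stays open as an untested biological explanation, and so does a change within macrophages, which also make C2, C3 and CFB. For the 1096 calls chance is unlikely, since only the real grouping, 1 of 100 splits of the 28 biopsies, gave as many. The highest other gave 140. With 100 splits chance is not excluded, and the splits take each biopsy as a separate person, which the labels do not show.

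Immediate early genes were lower after transplantation in living-donor kidneys, by 2.15 on average over 18 genes. Scaling between arrays is argued against as the whole cause, since the shift was -2.14 ± 0.233 (SE) in the values as deposited. With the GAPDH degradation measure as a covariate it was -2.14 ± 0.229 (SE). That measure was 1.47 in later and 1.54 in baseline biopsies, so as a covariate it could hardly move the shift. The fit therefore does not decide on degradation. Handling of the baseline biopsies before fixation cannot be told apart from time, because every baseline biopsy and no later one was taken at that stage, and the deceased-donor kidneys had a shift of -2.23 ± 0.408 (SE). A response of the kidney to surgery and loss of blood flow may equally underlie it and was not tested. Only the real grouping, 1 of 100 splits, gave as many calls as the 2890 in living-donor kidneys (highest other 1). The same held for the 2595 in deceased-donor kidneys (1 of 100, highest other 1). Chance is thus unlikely for both counts, though 100 splits do not exclude it.

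Test set 1 gave 1 call against 793 in the training set. Sample size may account for this: 33 of 100 draws of 5 and 5 training biopsies gave at most 1 call, with a median of 5 and a range of 0 to 500. Chance cannot be excluded for the single call, since 5 of 100 splits gave at least as many, which lies at the limit, and 11 of 100 did in the first draw. The highest other was 29 in both draws, which can come from a structure of the samples or from genes that vary together, and neither was tested. Chance is unlikely, though not excluded by 100 splits, for the 793 training calls (1 of 100, highest other 248). The same holds for the 32 calls repeated in test set 1 (1 of 100, highest other 1).

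The change after transplantation differed between donor types for 284 genes by the interaction test, and 1 of 100 splits, the real one, gave as many. The highest other split gave 221, so other groupings of the same samples can give counts of nearly this size. Among single genes the difference of changes was -2.08 for CNR1, 1.40 for CTSF, 1.92 for WIF1 and 1.29 for ETV5. Among complement genes it was -1.88 for C1QB, -1.80 for C1R, -1.66 for C1S, -2.01 for C2, -2.04 for CFB, -1.69 for C6, -1.09 for CLU, -2.19 for VSIG4 and 1.63 for CR1. These values contain the baseline donor differences with the sign turned and are not separate from them.

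By list, the mean difference of changes was -0.525 for all complement genes, -0.806 for the classical and lectin pathways and -1.49 for the alternative pathway with C3. It was 1.16 for metallothioneins, where 6 of 7 passed alone, -1.17 for acute-phase genes, -0.401 for the unfolded protein response, -0.462 for proliferation and -0.122 for oxidative phosphorylation. For cell markers it was 0.719 in the proximal tubule, -0.648 in the thick ascending limb, 0.674 in podocytes and 0.511 in T and NK cells. All of these were called by camera, and none passed with an estimated correlation (smallest adjusted p 0.0739). With fry, the thick ascending limb (adjusted p = 0.0588), podocytes (0.133), T and NK cells (0.294), oxidative phosphorylation (0.352) and the proximal tubule (0.39) did not pass.

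Within small groups, 28 tests looked for 1 biopsy far from the others in the degradation measures, the deposited array median or the complement list mean. In 4 of them 1 biopsy stood far off, where chance gives about 1 in 20. Some groups share biopsies, so the tests are not independent. The deposited array median was 3.83 in 1 deceased-donor training biopsy, against 4.23 to 4.45 in the others. The ACTB degradation measure was 8.06 in 1 living-donor training biopsy, against 3.80 to 5.71. The GAPDH measure was 2.49 in 1 living-donor biopsy of test set 1, against 1.03 to 1.42, and 5.10 in 1 deceased-donor biopsy of test set 2, against 0.91 to 2.64.

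Probe sets that carry no single gene symbol took no part in the comparisons. Among 9333 of these, 276 differed between donor types at baseline (limma), 127 higher and 149 lower in deceased-donor kidneys.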

How the results depend on the processing

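The macrophage covariate and the fits without 5 arrays that stood apart were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the labels name a paired set without saying which baseline biopsy belongs to which later one, and replicate numbers follow deposition order only. The change of pseudocount was not run, since the values were already log2, and the complement shift was not taken over all probe sets. No array that stood apart was in the baseline comparison, the training set, test set 1 or test set 2, so these had no such fit. No complement shift and no named gene turned its direction, but the balance of higher and lower calls did in places. At baseline it went from 627 higher and 469 lower to 311 and 353 at a fold of at least 1.5, and in the training set from 393 and 400 to 577 and 326 in the values as deposited. With averaged probe sets it went from 1694 and 1196 to 1505 and 1618 in living-donor kidneys and from 1384 and 1211 to 1158 and 1503 in deceased-donor kidneys, where it also turned with a filter at the median level (1252 and 1263), all probe sets (3132 and 3496) and array weights (1774 and 1824). In the training set it also turned with a filter at the median level (508 and 452), trend and robust variance (475 and 439), array weights (1070 and 991) and the GAPDH covariate (537 and 462). Of the counts of called genes 85 stayed within 1.5 times and 32 did not, of the complement shifts 86 stayed on their side of the threshold (camera adjusted p), 5 weakened and 2 strengthened, and of the named-gene values 1747 stayed, 62 weakened and 9 strengthened. Trend and robust variance cannot move a complement shift, only its p, and camera took the trend alone. Of the weakened named-gene values, 14 came from 3 months alone, 9 from 6, 5 from 12, 9 from 24 and 13 from averaged probe sets. A count of called genes that stayed within 1.5 times need not hold the same genes. Averaged probe sets kept 695 of the 1096 main calls at baseline and 175 of the 284 of the interaction. They kept 2349 of the 2890 in living-donor kidneys and 1932 of the 2595 in deceased-donor kidneys.

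The baseline count of 1096 became 664 at a fold of at least 1.5, 2225 with array weights and 707 with all 95 arrays in the fit, and the training count of 793 became 2061 with array weights. The test set 1 count of 1 became 2 with values as deposited, 2 with a filter at the median level, 2 with averaged probe sets, 2 with all probe sets, 2 with trend and robust variance, 15 with array weights and 0 with the GAPDH covariate. Leaving out 1 biopsy gave 0 to 5, with 5 without living-donor baseline replicate 10 and 0 without living-donor replicates 11, 12 and 13 or deceased-donor replicates 10, 12, 13 and 14; without living-donor replicate 14 the 1 call was another gene. The 32 repeated training calls became 61 with a filter at the median level, 54 with all probe sets, 59 with trend and robust variance and 72 with array weights, and 13 to 65 when 1 biopsy was left out (65 without living-donor replicate 10, 13 without 12).

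The living-donor count of 2890 became 1550 at a fold of at least 1.5, 6060 with all probe sets, 1287 at 3 months alone, 1428 at 6 and 1295 at 24, and the deceased-donor count of 2595 became 1662 and 6628 with the first 2 of these. The interaction count of 284 became 1030 with array weights and 456 with the GAPDH covariate. The F test over time gave 1 gene with no filter, 2 with array weights and 1 with a linear trend, and 24 against 3 months gave 1 with the GAPDH covariate. The complement shift in test set 2 (0.183, camera adjusted p = 0.0806) passed only with the GAPDH covariate (0.197, adjusted p = 0.0445). Between 24 and 3 months (0.126, adjusted p = 0.047) its call was lost with no filter (0.0835, 0.222), a filter at the median level (0.114, 0.11), averaged probe sets (0.0816, 0.0715) and the GAPDH covariate (0.105, 0.0741), while it was 0.217 (0.00135) with array weights and 0.193 (0.00377) without the arrays that stood apart. With the macrophage covariate it was 0.105 in living-donor and -0.315 in deceased-donor kidneys. Fold limits, single time points and all probe sets change the number of genes or biopsies by construction; for the others the cause was not tested.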

Other observations

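The split tests in this part were planned, but the splits were drawn again after a first draw had been seen, to remove repeated splits. For 4 comparisons limma called 0 genes, so each of the 100 splits gave at least as many by construction and the test says nothing about chance. The highest count among the other splits was 3 for donor type in the later biopsies, 58 for donor type in test set 2, 30 for limma's F test over time and 5 for 24 against 3 months. In the first draw these were 533, 1, 1 and 1, so they depend on which splits were drawn. The 4 comparisons had 920, 333, 890 and 545 genes at an unadjusted p under 0.05. Single splits that call many genes where the real grouping calls 0 can come from a structure of the samples or from genes that vary together, and neither was tested.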
